A study of Homo sapiens with 45 samples.

How the data were processed

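Single H1 cells were profiled with Smart-seq2 cDNA synthesis and Nextera XT libraries, per the labels' protocols. Each deposited sample is 1 cell, labelled as live (DAPI-) or fixed (DAPI+) and as prepared by FRISCR or by Triton lysis. The authors deposited 2 tables with a column per cell and 23045 genes. One holds estimated counts per gene (expected_counts), in which 40.3% of nonzero values are not whole, and the other holds tpm values by the authors. The genome build was GRCh37 (hg19) per the submitters' processing notes. The aligner, quantifier and gene annotation are not given in the sources used here. Neither table lists a row beginning with MT- or a spike-in row. Of the rows, 19074 carry a current and 1866 an older symbol of GENCODE release 29 and 2105 match neither, among them the abundant rows TVAS5, BC018860, OK/SW-cl.16, STRF6 and cytochromeb. Transcript length (of the longest transcript) and GC content came from that release by symbol and covered 97.8% to 98.2% of the genes compared.

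Counts were rounded to whole numbers and no cell was left out. Totals ranged from 3388417 to 6594043 per cell. The 4 groups were compared in 4 contrasts: fixed over live within FRISCR, fixed over live within Triton, FRISCR over Triton in live cells and FRISCR over Triton in fixed cells. The difference of both fixation effects was taken as well. Since the labels name no separate cultures, each group counted as 1 sample, and no p-value, standard error or count of changed genes was computed. Comparisons were also computed within each of 2 library sets.

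Genes detected were counted after thinning each cell at random to 1000000 counts. For gene folds, counts were summed over the cells of a group and divided by the summed total (CPM). Each ratio carries an exact 95% interval from the binomial split of the 2 counts, and a sum of 0 was set at a floor of 3 counts over the group. Correlations of single cells used log2(CPM + 1) of 8543 genes with a mean of at least 10 CPM. The repeatability of folds, the trends with length and GC content and the shares within 2-fold used genes with at least 20 CPM in either group. Detection by expression level used 5 bins of 2042 genes.

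Gene lists, 28 in all, were fixed before the data were examined, as was every setting not named here or below as added. They cover pluripotency and naive-state pluripotency, the cytosolic ribosome, oxidative phosphorylation, translation factors, glycolysis, stress and immediate early responses, p53 targets, nuclear noncoding RNA, replication-dependent histones, small structured RNA, mitochondrially encoded RNA, the cell cycle, matrix, cell surface, cytoskeleton, cholesterol biosynthesis, spike-ins and markers of other cell types. A list was measured if it had at least 3 members with a mean of at least 5 CPM. Its median log2 fold was placed among 10000 random lists of the same size drawn from 20 bins of expression. A list stands apart when it lies outside the central 95% of these and keeps its side of the median of all genes in both library sets. This describes these libraries and is no test. The median of all genes, unlike the random lists, was not matched on expression. A list's side within a set can therefore also reflect its expression level. Single genes were named by a rule: the 12 highest and 12 lowest by the smaller log2 fold of the 2 sets, among genes with at least 50 CPM in both sets in the group where they are higher, a count in at least 60% of that group's cells and the same direction in both sets. From each list the rule took the 3 most abundant members and the most extreme one each way with at least 10 CPM. For the difference of fixation effects it took the 5 genes each way with the largest difference of the same sign in both sets, at 50 CPM or more in 1 of the 4 groups in both sets. The rule passed over Y-linked genes and XIST.

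Alternatives for normalization were TMM (edgeR 4.0.16) and median-of-ratios (DESeq2 1.42.0) in R 4.3.3, means of per-cell CPM, means of TPM, and totals without the rRNA-named and the 5 unmatched abundant rows. The last was added after the data were seen, as were random lists matched on transcript length, the length implied by the authors' counts and TPM, the shares of TVAS5 and of 44 rRNA-named rows, the values within library sets for correlations, shares and length, the leaving out of single cells for genes detected and correlations, and the other scalings of the difference of fixation effects. Other alternatives changed the thinning depth, detection minimum, pseudocount, gene filters and correlation measure, or left out each cell in turn. The procedure was tested on simulated data with 50 genes at each of 4 known folds. For the 2 contrasts given here both groups were drawn from the summed live profile, with the same fixed spread over cells and no further loss of transcripts. The real sets of fixed Triton cells differed by a median log2 of 1.85, against 0.48 for live Triton cells. The simulation therefore does not show how well folds are recovered in fixed Triton cells. For true log2 folds of -2, -1, 1 and 2 the median recovered was -2.05, -1.04, 0.87 and 1.90 with the group sizes of fixed over live FRISCR, with the right sign for 100%, 98%, 88% and 100% of genes, and -1.91, -1.34, 0.97 and 1.97 with those of fixed over live Triton, with the right sign for 98%, 96%, 92% and 100%. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.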

Results

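The data were transcript profiles of 45 single cells of H1, an established human embryonic stem cell line, at passage 40. Per the series' design line, live and fixed cells were each prepared by FRISCR, a procedure for recovering RNA from fixed single cells, and by plain lysis in the detergent Triton X-100, to test the principle of FRISCR. The groups follow the labels' sample group; the titles carry other codes, PLRC for FRISCR and RLT for Triton cells, and the labels' extraction protocol describes cortical tissue. FRISCR gave 15 live and 12 fixed cells, and Triton lysis gave 11 live and 7 fixed cells. A code shared by the sample titles splits each group into 2 library sets, of 8 and 7 live FRISCR, 6 and 6 fixed FRISCR, 5 and 6 live Triton, and 4 and 3 fixed Triton cells. Total counts ranged from 3388417 to 6594043 per cell, with medians of 4786207 in live FRISCR, 4452107 in fixed FRISCR, 4994021 in live Triton and 4301153 in fixed Triton cells. The labels name no separate cultures, so each group is 1 sample, cells are not replicates, and no test was possible on any difference between groups. Intervals are 95% counting intervals on summed counts. They cover counting error only, since reads without molecular identifiers are not independent molecules.

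The comparison of fixed with live FRISCR cells asks what fixation changed when RNA was recovered by FRISCR. Genes of oxidative phosphorylation, the mitochondrial pathway of ATP synthesis, were higher in fixed cells, with a median log2 fold of 0.33 over 72 members, against -0.03 for all genes measured beside the lists. Cytosolic ribosomal protein genes, the protein part of the ribosome, were also higher, with a median of 0.26 over 77 members. G1/S genes, which prepare and carry out DNA replication, were lower, with a median of -0.33 over 39 members. Pluripotency genes lay near all genes, at -0.11 over 26 members, and their most abundant member CD24, a surface glycoprotein, stood at 2831 counts per 1000000 (CPM) in fixed and 2885 in live cells. The lists of oxidative phosphorylation, ribosomal protein and G1/S genes each stood outside the central range of random lists of the same size and expression, with percentiles of 100, 100 and 0. Against random lists matched on the transcript length implied by the files, an alternative added after the data were seen, the ribosomal protein list lay at percentile 24.14, with a matched median of 0.29.

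The median was 0.39 in set 1 and 0.31 in set 2 for oxidative phosphorylation and 0.17 and 0.31 for ribosomal protein genes. Of the oxidative phosphorylation members, 64 exceeded the median of all genes in both library sets and 1 lay below it in both. The complex I subunit NDUFB5 had 146 CPM in fixed and 76.5 CPM in live cells (log2 0.94), cytochrome c (CYCS) had a log2 fold of 0.26, and the complex I subunit NDUFS1 had -0.32. Of the ribosomal protein members, 68 exceeded the median of all genes in both sets, RPS26 with a log2 fold of 0.62 at one end and the abundant RPL3 with -0.20 at the other. Of the G1/S members, 22 lay below the median of all genes in both sets and 3 above it. They included MCM3, a subunit of the replicative helicase, with 314 CPM in fixed and 556 CPM in live cells (log2 -0.83), and the chromatin assembly factor subunit CHAF1B (log2 -1.94). The G1/S median was -0.55 in set 1 and -0.14 in set 2. The neural and radial glia list also stood apart, at -0.67 over 7 members (percentile 1.03). PTPRZ1, a receptor phosphatase of neural progenitors, had a log2 fold of -0.67 and the fatty acid binding protein FABP7 had 0.75. Its sets gave only -0.24 and -0.15, and without live FRISCR replicate 12 its distance from all genes went from -0.64 to 0.12.

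The other 14 lists did not stand apart between fixed and live FRISCR cells. Their medians were 0.11 for translation factors, -0.03 for glycolysis, -0.01 for heat shock and chaperone genes, -0.08 for the unfolded protein and amino acid response, and -0.02 for p53 targets and apoptosis. They were -0.20 for immediate early genes, -0.22 for nuclear-retained long noncoding RNA, -0.03 for G2/M genes, -0.05 for cytoskeleton, -0.10 for cell surface and adhesion, -0.10 for extracellular matrix, -0.14 for cholesterol biosynthesis and -0.06 for fibroblast genes.

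Among single genes that were higher in fixed than in live FRISCR cells in both sets, the transcription factor EGR1, an immediate early gene, had 81.4 CPM against 24.5 CPM (3.32-fold, 3.14 to 3.51). It depended on 2 cells, with 1.93-fold without fixed replicate 3 and 2.12-fold without fixed replicate 8. MLL5, a regulator of the cell cycle and chromatin, was 2.35-fold higher. SEL1L, an adaptor for degrading misfolded proteins of the endoplasmic reticulum, was 5.92-fold lower (5.48 to 6.41), and 9.12-fold lower without fixed replicate 5. EIF2AK2, the kinase PKR that senses double-stranded RNA, was 4.15-fold lower, and 6.54-fold lower without fixed replicate 11. The scaffold protein DNMBP was 5.90-fold lower and the axon guidance ligand SEMA3A 4.29-fold lower. The 12 genes named each way ranged from 2.13-fold to 3.79-fold higher and from 2.83-fold to 5.92-fold lower.

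Fixed and live FRISCR cells differed little in genes detected at equal depth. After thinning every cell to 1000000 counts, the median was 8924.5 genes in fixed cells (SD over cells 592, range 8012 to 10005) and 9066 in live cells (SD 524, range 8363 to 10321), a difference of -142 that is smaller than the SD over cells. It was -184 in set 1 and -161 in set 2, and leaving out a fixed cell moved it to -223 (6 of the 12 cells, such as fixed replicate 3) or -60 (the other 6, such as fixed replicate 1). Ribosomal protein genes took a median of 7.14% of counts in fixed cells (SD 1.12) and 5.64% in live cells (SD 0.767), with 6.04% against 5.37% in set 1 and 7.72% against 6.53% in set 2. Of 7518 genes with at least 20 CPM, 89.0% lay within 2-fold, 7.69% were more than 2-fold lower and 3.34% more than 2-fold higher. The median size of the log2 fold was 0.36 for all cells and 0.46 within the sets, and the sets of one group differed from each other by medians of 0.44 and 0.49. Folds in set 1 and set 2 correlated at r = 0.15 across genes, which are not independent replicates. The correlation of single cells had a median of 0.530 among live cells and 0.518 between fixed and live cells, and the summed profiles correlated at 0.922. The median log2 fold went from 0.19 in the shortest 20% of transcripts to -0.14 in the longest 20%, so the short transcripts of ribosomal protein and oxidative phosphorylation genes sit where folds were highest, and over GC content it was -0.03 in the lowest 20% and -0.05 in the highest, with opposite trends in set 1 (-0.07 to 0.0073) and set 2 (0.06 to -0.12). The median of all genes was -0.02 by total counts and -0.14 by mean TPM.

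**Figure D1:**
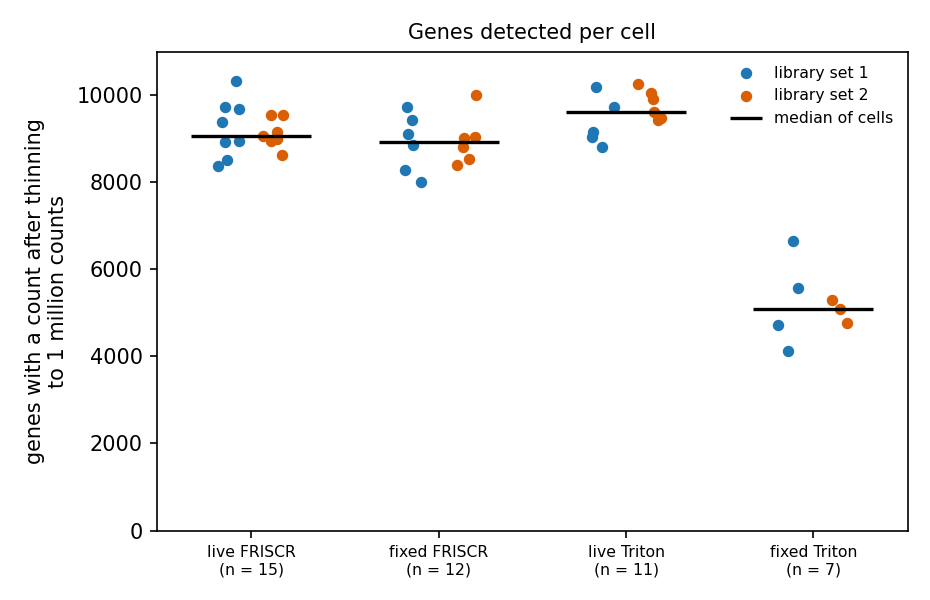
Genes with at least 1 count in each cell after thinning to 1000000 counts, by group, with points for single cells, colours for the 2 library sets and bars for group medians. The 7 fixed Triton cells lie between 4121 and 6637 genes, below each of the other 38 cells.

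The comparison of fixed with live Triton cells asks the same of plain detergent lysis. Most genes were lower in fixed cells, while 3 groups stood far above the rest. Ribosomal protein genes had a median log2 fold of 1.27, oxidative phosphorylation genes 0.75, and replication-dependent histone genes, whose proteins package newly made DNA and whose mRNA lacks a poly(A) tail, 1.82, against -1.51 for all genes measured beside the lists. G2/M genes, which act in mitosis, were the lowest called group, at -3.11 over 49 members. Pluripotency genes had a median of -1.54 over 27 members, near all genes, but within the sets they lay above all genes, at -1.46 and -1.40 against -2.15 and -2.60, with 14 members above in both sets and 4 below. They include POU5F1 (OCT4, a core factor of the embryonic stem cell state) with 315 CPM in fixed and 905 CPM in live cells. Without thinning, 312 (set 1) and 644 (set 2) of 2042 genes in the middle expression bin had no count in fixed Triton cells. In the highest bin these were 11 and 79. The median of all genes is not matched on expression, so the side of pluripotency genes within the sets may reflect their expression level.

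All 77 ribosomal protein members exceeded the median of all genes in both sets. RPLP0, a stalk protein of the large subunit, had 5024 CPM in fixed and 1670 CPM in live cells, RPS29 had 1105 and 196 CPM, and RPL4, the lowest, stood at log2 -0.83. Of 72 oxidative phosphorylation members 62 exceeded the median of all genes in both sets and 3 lay below it, with the small subunits NDUFA4 at 1.80 and UQCR10 at 2.06 and the ATP synthase beta subunit ATP5B at -2.72. Of 17 histone genes 15 exceeded it in both sets, and HIST1H4C had 1657 CPM in fixed and 423 CPM in live cells. Of 49 G2/M members 24 lay below all genes in both sets and 9 above, and the DNA topoisomerase TOP2A had 56.1 CPM in fixed and 570 CPM in live cells. The percentiles were 100 for the first 3 groups and 0 for G2/M genes. The medians in sets 1 and 2 were 1.17 and 1.28 for ribosomal protein, 0.41 and 1.07 for oxidative phosphorylation, 1.13 and 2.38 for histone and -3.45 and -3.25 for G2/M genes. The other 15 lists did not stand apart, although heat shock and chaperone genes (-2.08), glycolysis genes (-1.96), the unfolded protein and amino acid response (-2.45), cell surface and adhesion genes (-2.09) and cytoskeleton genes (-1.56) had percentiles of 0.64, 0.91, 0.91, 1.85 and 2.22. Their set medians did not keep to 1 side of all genes, or lay on the other side: -2.18 and -1.83, -1.78 and -1.67, -1.77 and -5.85, -1.85 and -2.68, and -1.45 and -1.63. In those lists members parted: the chaperone HSPA5 stood at log2 -3.41 and the calcium-binding chaperone CALR at 1.38, GAPDH at -0.24 and ENO1 at -1.98.

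Single genes differed between fixed and live Triton cells by up to 3 orders of magnitude. PSMC6, an ATPase subunit of the proteasome, had 6 counts in all fixed cells and 15147 in live cells (1273-fold lower, 585 to 3468), and 2196-fold lower without fixed replicate 4. The transferrin receptor TFRC had 0 counts against 213.7 CPM, at least 2076-fold lower with the floor of 3 counts over the group. In the other direction, the intermediate filament protein SYNC had 151 CPM in fixed and 0.605 CPM in live cells (250-fold higher, 180 to 360) and counts in 7 of 7 fixed cells. SPNS2, a transporter of sphingosine 1-phosphate, had 1741 against 3 counts, a ratio of 1151 (393 to 5588). The splicing factor HNRNPL was 6.11-fold higher, the mitochondrial protein CHCHD5 6.09-fold higher, and the row c21_SSU-rRNA_Hsa, named for small-subunit ribosomal RNA, 6.83-fold higher.

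Fixed Triton cells had a median of 5086 genes after thinning (SD 795, range 4121 to 6637) against 9616 in live Triton cells (SD 476, range 8803 to 10244), a difference of -4530 that was -3994.5 in set 1 and -4682 in set 2. The row TVAS5 took a median of 26.3% of counts in fixed cells (range 16.2% to 33.0%) and 6.90% in live cells (2.76% to 13.0%). Rows named for rRNA took 9.00% (6.09% to 11.4%) and 1.26% (0.565% to 1.90%), and the 100 highest genes of each cell 59.5% and 28.5%. Ribosomal protein genes took 10.0% of counts in fixed cells (SD 1.77) and 4.90% in live cells (SD 0.586). Summed over fixed Triton cells, TVAS5 took 24.5% of counts (exact binomial interval 24.48% to 24.51%) and rRNA-named rows 8.59% (8.58% to 8.60%).

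Of 7256 genes with at least 20 CPM, 58.5% were more than 2-fold lower in fixed than in live Triton cells, 12.4% more than 2-fold higher and 29.1% within 2-fold. The median size of the log2 fold was 1.82 for all cells and 2.51 within the sets, and the sets of fixed Triton cells differed from each other by 1.85 and those of live Triton cells by 0.48. Folds in the 2 sets correlated at r = 0.34 across genes. The correlation of single cells had a median of 0.573 among live cells and 0.352 between fixed and live cells, and the summed profiles correlated at 0.526. The median log2 fold was -0.34 in the shortest 20% of transcripts, between -2.12 and -1.59 in the other 4 length bins, -1.93 in the lowest 20% by GC content and -0.98 in the highest. In the middle of 5 bins of genes by expression, a gene had a count in 37.6% of fixed and 86.6% of live Triton cells, and in the highest bin in 74.1% and 99.8%. The median of all genes depended on the scaling: -1.501 by total counts, -0.89 with the abundant rows left out of the total, -0.48 by TMM, -0.30 by median-of-ratios and -1.98 by mean TPM. By mean TPM the groups above kept their side of this median. TMM, median-of-ratios and totals without the abundant rows shift all genes alike, so a list's side cannot change under them. Ribosomal protein, oxidative phosphorylation and histone genes stayed above 0 under each scaling.

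**Figure D2:**
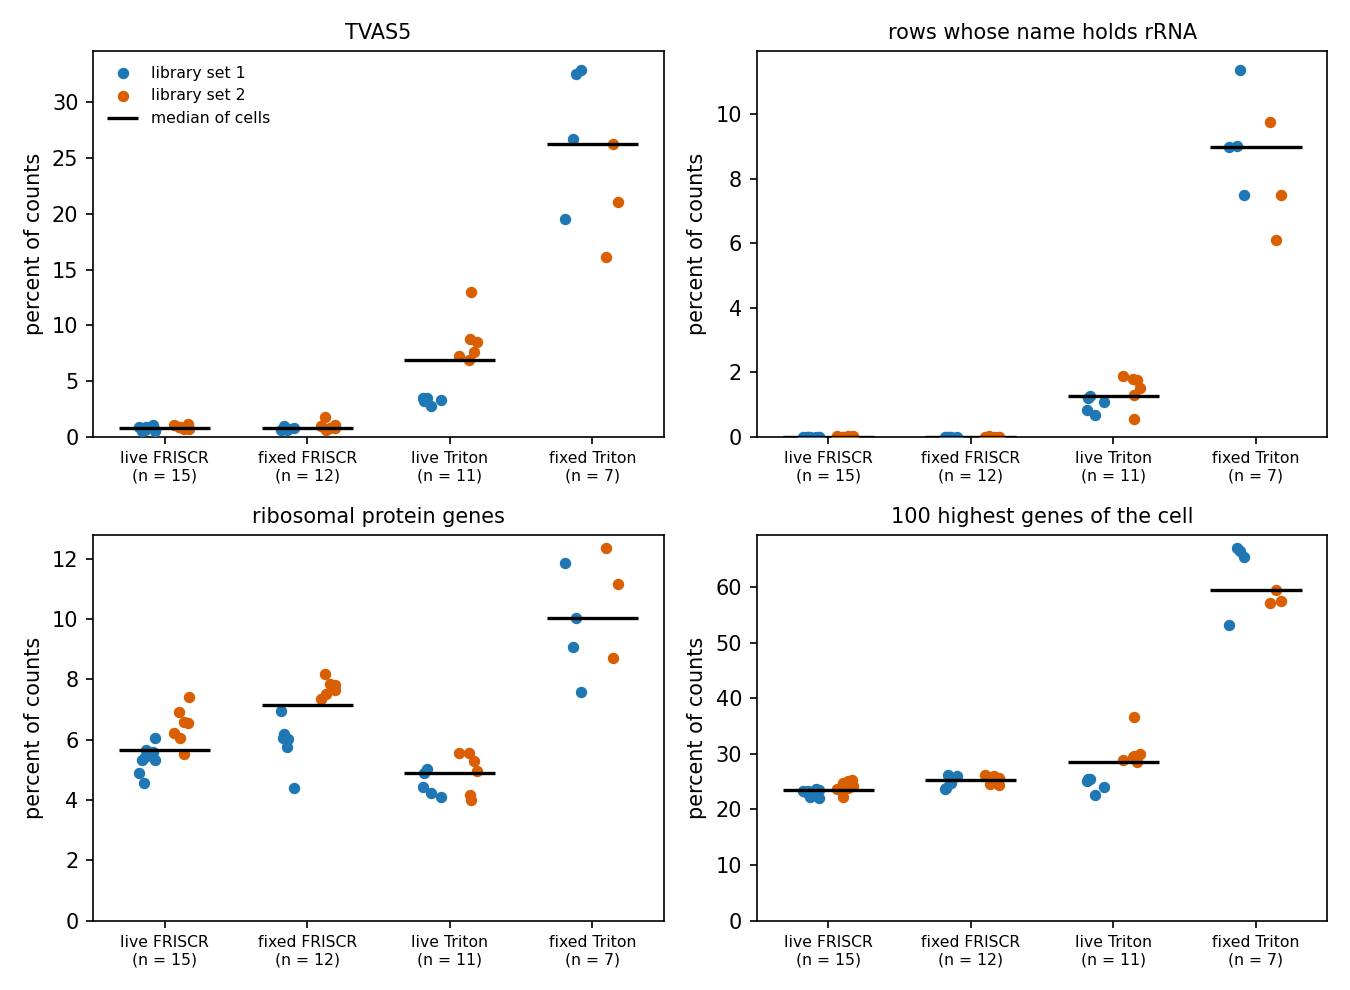
Percent of each cell's counts taken by TVAS5, by rows named for rRNA, by ribosomal protein genes and by the 100 highest genes, with points for single cells, colours for the 2 library sets and bars for group medians. The median share of TVAS5 is 26.3% in fixed Triton, 6.90% in live Triton, 0.826% in live FRISCR and 0.773% in fixed FRISCR cells.

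The comparison of FRISCR with Triton lysis in live cells asks what the preparation changed without fixation. Several RNA species were much lower with FRISCR. Replication-dependent histone genes had a median log2 fold of -6.35 over 9 members, against 0.11 for all genes, and HIST1H4C had 4.59 CPM with FRISCR and 423 CPM with Triton (92.3-fold lower, 82.9 to 103.2). MALAT1, a long noncoding RNA kept in the nucleus, was 7.98-fold lower (149 against 1192 CPM), although the nuclear-retained long noncoding RNA list had a median of 0.48 over 5 members, and the row c21_SSU-rRNA_Hsa was 394-fold lower (377.0 to 412). TVAS5 was 7.86-fold lower and MTRNR2L2, a nuclear gene similar to mitochondrial 16S rRNA, 7.04-fold lower. Pluripotency genes were slightly higher with FRISCR, at a median of 0.25 over 26 members.

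Of the 9 histone genes, 8 lay below all genes in both sets, and HIST1H1D had 0 counts with FRISCR against 34.4 CPM with Triton, at least 831.5-fold lower. Of the pluripotency members, 10 lay above all genes in both sets and 3 below. CD24 was at log2 0.65, the RNA-binding protein LIN28A at 0.37 and GDF3, a ligand of the TGF-beta family, at 1.47. Ribosomal protein genes (0.33, with 56 of 77 members above all genes in both sets), cholesterol biosynthesis (0.37, 10 of 20) and cell surface and adhesion (0.38, 14 of 28) were higher with FRISCR. The gap junction protein GJA1 had 349 against 146 CPM, and the mevalonate pathway enzyme MVD had 151 against 80.6 CPM. Extracellular matrix genes also stood apart, at 0.36 (percentile 97.6), with the laminin LAMA5 at log2 2.47 and fibronectin FN1 at -1.49. G2/M genes were lower, at -0.09, with 24 of 49 members below all genes in both sets and 4 above, and CDCA2, a regulator of mitotic chromatin, at -1.47. The percentiles were 98.1 for pluripotency, 100 for ribosomal protein and 99.9 for cholesterol genes, 99.99 for cell surface genes, and 0 and 0.28 for histone and G2/M genes. The other 12 lists did not stand apart; oxidative phosphorylation lay at 0.09 by total counts and -0.02 by median-of-ratios.

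Among single genes higher in live FRISCR than in live Triton cells, TMED9, a cargo receptor of the early secretory pathway, was 3.76-fold higher (3.61 to 3.91). The long noncoding RNA MIAT was 2.84-fold higher, the fatty acid desaturase FADS2 2.83-fold, the sister chromatid cohesion factor DSCC1 2.91-fold, the hyaluronan synthase HAS3 2.65-fold and the survival factor BCL2L1 2.44-fold.

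Live FRISCR cells had a median of 9066 genes after thinning and live Triton cells 9616, a difference of -550 that was 20.5 in set 1 and -702 in set 2 and so changed sign between sets. TVAS5 took a median of 0.826% and 6.90% of counts, with 2.76% to 3.47% in set 1 and 6.90% to 13.0% in set 2 of live Triton cells, and rRNA-named rows took 0.00428% and 1.26%. Each of the 15 live FRISCR cells lay below all 11 live Triton cells in both shares and in MALAT1. Of 7447 genes, 90.3% lay within 2-fold, 6.57% were more than 2-fold higher and 3.14% more than 2-fold lower with FRISCR. The median size of the log2 fold was 0.34 for all cells and 0.46 within the sets, against 0.43 and 0.48 between the sets of one group, and folds in the 2 sets correlated at r = 0.26 across genes. Single cells correlated at a median of 0.541 between methods, and the summed profiles at 0.919. The median log2 fold was 0.12 in the shortest and 0.04 in the longest 20% of transcripts, and 0.05 and 0.20 in the lowest and highest 20% by GC content. Both trends ran the other way in set 1, from -0.07 to 0.07 over length and from 0.16 to 0.05 over GC content, and set 2 gave 0.28 to -0.04 and -0.08 to 0.36. The median of all genes was 0.10 by total counts and 0.02 by TMM.

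**Figure D3:**
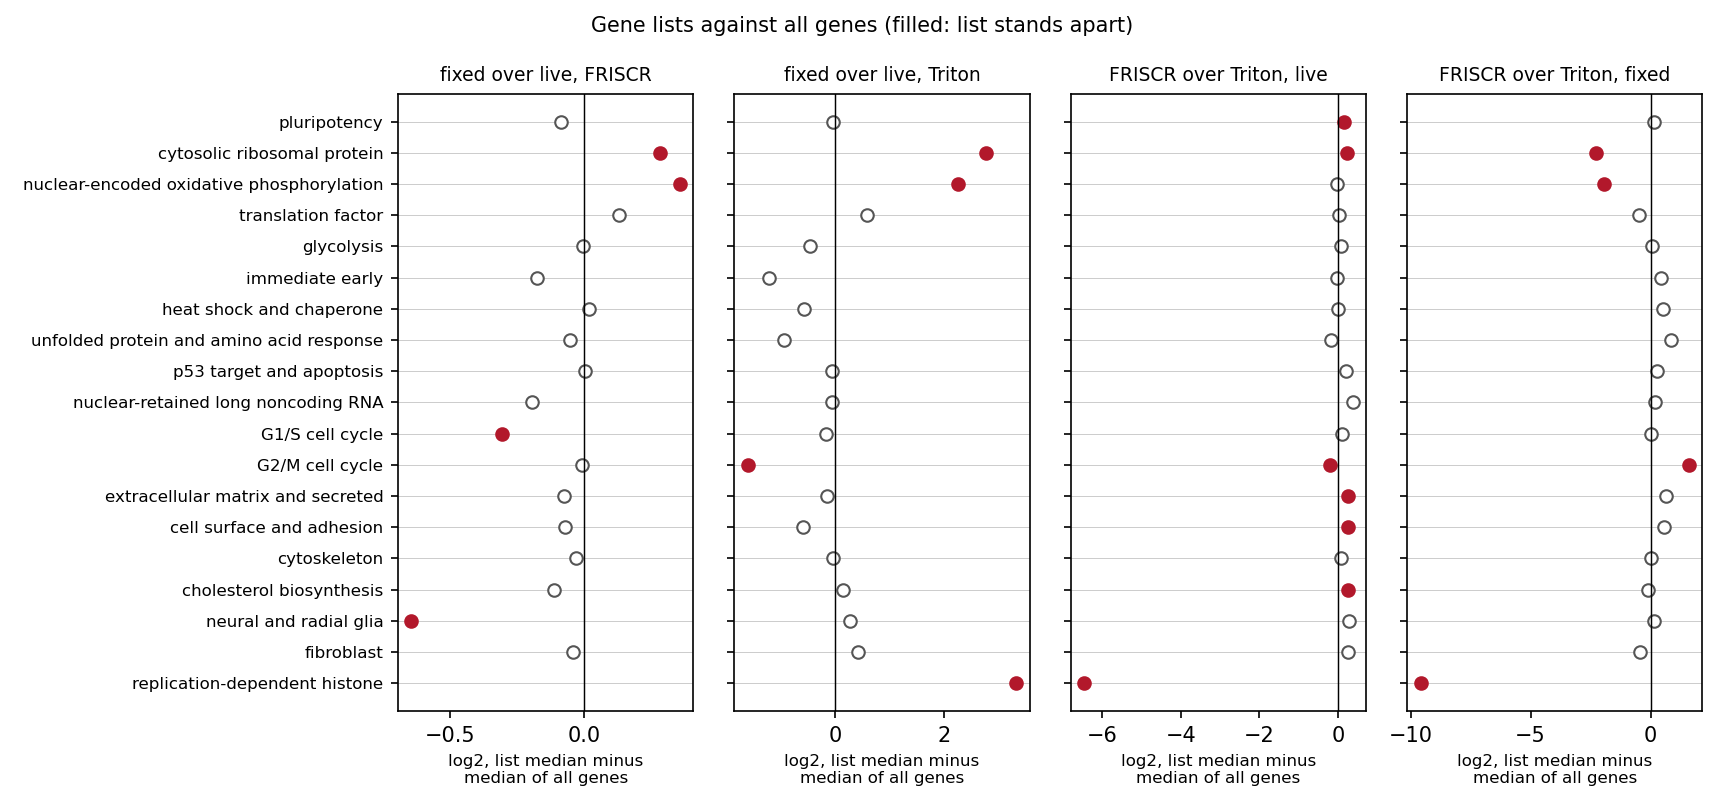
Median log2 fold of each gene list minus the median of all genes in the 4 comparisons, with filled points for lists that stand apart from random lists and keep their side in both library sets. Ribosomal protein genes stand apart from random lists of the same size and expression in each comparison, though not in fixed over live FRISCR cells once lists are matched on the length implied by the files, above all genes in the first 3 and below them in fixed FRISCR over fixed Triton cells.

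The comparison of FRISCR with Triton lysis in fixed cells asks which method kept more of the transcriptome after fixation. Most genes were higher with FRISCR, at a median log2 fold of 1.59 for all genes measured beside the lists. Pluripotency genes had a median of 1.73 over 27 members, but within the sets they lay below all genes, at 1.78 and 1.45 against 2.18 and 2.64, with 4 members above in both sets and 14 below. They include POU5F1 with 1114 CPM with FRISCR and 315 CPM with Triton. Here too the median of all genes is not matched on expression, so this side within the sets may reflect expression level. G2/M genes lay higher, at 3.20 over 49 members. Replication-dependent histone genes lay lowest, at -7.99 over 16 members, followed by ribosomal protein genes (-0.70) and oxidative phosphorylation genes (-0.37, but 0.14 by mean TPM, where all genes were at 1.89).

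All 16 histone genes and all 77 ribosomal protein genes lay below the median of all genes in both sets. The linker histone HIST1H1E had 0 counts with FRISCR and 142 CPM with Triton, at least 2601-fold lower, and HIST1H4C was 301-fold lower (268 to 338). Without fixed Triton replicate 7 the distance of the histone list from all genes went from -9.58 to -8.68. RPLP0 had 2519 CPM with FRISCR and 5024 CPM with Triton and RPS27 was at log2 -1.85, while RPL4 was at 1.12. Of the oxidative phosphorylation genes 62 lay below all genes in both sets and 4 above, with NDUFA4 at -1.15 and ATP5B at 2.89. Of the G2/M genes 22 lay above all genes in both sets and 9 below, and TOP2A had 514 CPM with FRISCR and 56.1 CPM with Triton. The percentiles were 0 for the histone, ribosomal protein and oxidative phosphorylation lists and 100 for G2/M genes, with medians in sets 1 and 2 of -7.13 and -7.73, -0.81 and -0.49, -0.18 and -0.50, and 3.33 and 2.93. The other 15 lists did not stand apart, although heat shock and chaperone genes (2.13), the unfolded protein and amino acid response (2.43), cell surface and adhesion genes (2.15) and cytoskeleton genes (1.602) had percentiles of 99.7, 99.4, 99.3 and 98.4, since their set medians did not both lie above all genes. PSMC6 had 322 CPM with FRISCR and 0.206 CPM with Triton (1566-fold higher, 719 to 4267, and 2702-fold without fixed Triton replicate 4). The rRNA row c21_SSU-rRNA_Hsa was 2993-fold lower with FRISCR (2837 to 3159) and c16_SSU-rRNA_Hsa 967-fold lower.

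Each of the 12 fixed FRISCR cells had more genes after thinning than all 7 fixed Triton cells, with medians of 8924.5 and 5086, a difference of 3838.5 that was 3831 in set 1 and 3819 in set 2. TVAS5 took a median of 0.773% of counts with FRISCR (range 0.591% to 1.77%) and 26.3% with Triton, and rRNA-named rows 0.00519% and 9.00%. Of 7272 genes, 59.8% were more than 2-fold higher with FRISCR, 10.6% more than 2-fold lower and 29.5% within 2-fold. The median size of the log2 fold was 1.80 for all cells and 2.46 within the sets, against 1.87 between the sets of fixed Triton cells and 0.48 between those of fixed FRISCR cells, and folds in the 2 sets correlated at r = 0.32 across genes. Single cells correlated at a median of 0.456 among fixed Triton cells and 0.365 between methods, and the summed profiles at 0.550. The median log2 fold was 0.68 in the shortest 20% of transcripts, 2.07 in the middle bin and 1.43 in the longest, and 1.82 and 1.18 in the lowest and highest 20% by GC content. In the middle expression bin, a gene had a count in 78.0% of fixed FRISCR and 37.6% of fixed Triton cells. The median of all genes was 1.53 by total counts, 0.82 with the abundant rows left out and 0.44 by TMM. It was 0.27 by median-of-ratios and 1.89 by mean TPM. By mean TPM the 4 lists above kept their side of this median. TMM, median-of-ratios and totals without the abundant rows shift all genes alike, so a list's side cannot change under them.

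**Figure D4:**
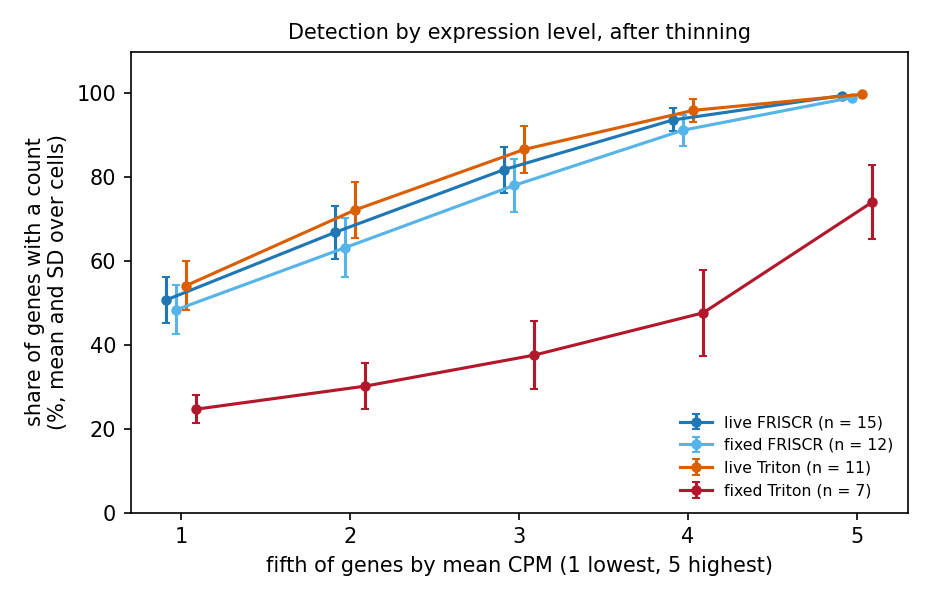
Share of genes with a count, as mean and SD over the cells of each group after thinning, in 5 bins of genes by mean CPM (2042 genes each). In the middle bin the mean is 37.6% in fixed Triton cells and between 78.0% and 86.6% in the other 3 groups.

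The fixation effect with FRISCR minus that with Triton compares 4 separate sets of libraries. G2/M genes had a median difference of 3.07 (log2), against 1.58 for all genes, oxidative phosphorylation genes -0.42 (-0.10 in set 1 and -0.74 in set 2, and 0.08 by mean TPM) and ribosomal protein genes -0.93. Pluripotency genes, at 1.62, lay near all genes for all cells but below them within the sets, at 1.55 and 1.48 against 2.15 and 2.56. All genes were not matched to them on expression. By TMM all genes lay at 0.57 and G2/M genes at 2.07. The 5 genes named for the largest positive differences each had 1 count in fixed Triton cells, where the floor of 3 counts holds genes with 0 counts to smaller differences. They were led by ERAL1, a chaperone of mitochondrial ribosome assembly, with a log2 fold of 0.63 under FRISCR and -12.14 under Triton, and by PAN3, a subunit of a poly(A) nuclease, with 0.87 and -11.73. The largest negative differences were in SYNC (0.38 and 7.97) and the deacetylase SIRT2 (-0.23 and 5.49, the first being 1.16 in set 1 and -6.54 in set 2). Across 8175 genes the fixation folds of the methods correlated at r = 0.12, and the FRISCR-over-Triton folds of live and fixed cells at r = 0.09.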

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

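The shares of TVAS5 and of rRNA-named rows entered the search for outlying cells only after the data were seen, and no test of the differences between methods below was run. Only the 7 fixed Triton cells form a group small enough for that search, which covered 14 per-cell measures and 20 named genes; a gap to the nearest cell that is large for the group's range arises by chance in about 1 of 20 groups. Fixed Triton replicate 1 had the lowest median correlation with its own group, 0.430. Replicate 3 stood out in 6 rows named for ribosomal RNA, the structural RNA of the ribosome: c16_SSU-rRNA_Hsa at 13474 CPM (next cell 7553), c2_SSU-rRNA_Hsa at 6048 CPM (next 2796), c17_LSU-rRNA_Hsa at 1111 CPM (next 284), c5_LSU-rRNA_Hsa at 519.7 CPM (next 89.7), c11_LSU-rRNA_Hsa at 465 CPM (next 127) and c5_SSU-rRNA_Hsa at 285 CPM (next 142). Replicate 5 was lowest in c1_LSU-rRNA_Hsa, at 464 CPM (next 798). Rows named for rRNA need not be independent of each other.

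Of the 10 genes named for the largest differences between the fixation effects, 3 went opposite ways with FRISCR and with Triton lysis in both library sets, by their folds as measured. Among lists that stood apart with either method, 1 did so after the median of all genes was taken off. Translation factors, a list that stood apart with neither method, had medians as measured of 0.08 and 0.10 under FRISCR and -0.81 and -0.97 under Triton. That contrast follows the scaling by total counts. By TMM and median-of-ratios they lay at 0.12 and 0.16 under FRISCR and at 0.09 and 0.27 under Triton, the same direction. ERAL1 differed by 12.77 (log2), PAN3 by 12.60, and HTATIP2, an oxidoreductase that affects apoptosis, by 12.27. Each had more CPM in fixed than in live FRISCR cells and 1 count in all fixed Triton cells. The neural and radial glia list differed by -0.92 once the median of all genes in each method was taken off. That difference depends on 1 cell, since the FRISCR value goes from -0.64 to 0.12 without live FRISCR replicate 12. It also depends on the members taken, since the FRISCR value is 0.39 with members from 1 count. The Triton value is 0.28 with members from 5 CPM, a different minimum.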

How the results depend on the processing

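Chosen after seeing the data were the totals without the abundant rows, the length implied by the files, the sets taken singly for correlations, shares and length, and the leaving out of single cells for genes detected and correlations. For the comparisons, 123 alternative values stayed within the spread over cells or sets, 49 moved and 4 changed sign. With 1 cell left out, 267 stayed and 3 moved. For correlations of folds between sets a fixed limit took the place of that spread. For the gene lists 575 stayed, 99 moved and 1 changed sign, and with 1 cell left out 1552 stayed, 130 moved and 1 changed sign. For lists a change of sign was counted only where the list stood apart. For correlations of cells, medians of all genes and shares it was counted only where the main value exceeded its spread. Other changes of sign are among those that stayed or moved, as for glycolysis in fixed over live Triton cells. TMM, median-of-ratios and totals without the abundant rows shift all genes alike, so under these a list's distance from all genes stays by construction. For the named genes 458 stayed and 214 moved, with 1839 and 321 when 1 cell was left out, and none changed sign. Where no reason is given, the cause was not tested. No paired analysis was possible because the replicate numbers only order the names. Leaving out cells of low depth, as planned, applied to 0 cells, and totals without rows beginning with MT- or spike-in rows were not run, since none is listed. The row cytochromeb was left out only together with the other abundant rows.

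Genes detected between live FRISCR and live Triton cells differed by -550, and by 20.5 in set 1 alone, the opposite sign. With 1 cell left out the difference lay between -606.5 and -482.5 there, between -4689.5 and -4425 for fixed and live Triton cells, between 3733.5 and 3998 for the methods in fixed cells, and between -223 and -60 for fixed and live FRISCR cells, against -142 with all cells. The fall in correlation between fixed and live Triton cells was 0.222, and 0.270 with log2(CPM + 10), 0.264 with all genes and 0.309 by Spearman. Between FRISCR and Triton in fixed cells it was 0.0909, and 0.0524 with log2(CPM + 10) and 0.0519 with all genes.

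The median of all genes between fixed and live FRISCR cells was -0.013 in set 1, -0.011 by TMM, -0.011 without the abundant rows, -0.14 by mean TPM, and 0.027, the opposite sign, by median-of-ratios. With 1 cell left out it lay between -0.032 and -0.016, the last without live FRISCR replicate 1. Between fixed and live Triton cells it was -2.10 in set 1, -2.27 in set 2, -0.48 by TMM, -0.30 by median-of-ratios, -1.98 by mean TPM and -0.89 without the abundant rows, and between -1.63 (without fixed Triton replicate 5) and -1.48 with 1 cell left out. Between FRISCR and Triton in live cells it was 0.018 by TMM, 0.00014 without the abundant rows, and -0.0092, the opposite sign, by median-of-ratios. In fixed cells it was 2.06 in set 1, 2.25 in set 2, 0.44 by TMM, 0.27 by median-of-ratios, 1.89 by mean TPM and 0.82 without the abundant rows, and between 1.503 and 1.66 (without fixed Triton replicate 2) with 1 cell left out. Leaving out rows that take a larger share in fixed Triton cells raises every other gene there by construction.

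The correlation of folds between sets was 0.37 from 100 CPM up for fixed over live FRISCR, 0.15 from 5 CPM and 0.46 from 100 CPM for the methods in live cells, and 0.45 from 100 CPM for the methods in fixed cells. The longest minus the shortest 20% of transcripts gave, for fixed over live Triton, -1.54 by the length implied by the files, -1.54 in set 1 and -1.81 in set 2. For the methods in live cells it gave 0.15 in set 1, against -0.07, the opposite sign. In fixed cells it gave 1.05 by the implied length and 1.28 in set 2.

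Shares are given as differences in percentage points. Ribosomal protein genes by TPM differed by 7.43 between fixed and live Triton cells and by 3.27 between methods in live cells. Rows named for rRNA differed by 14.9 by TPM and 5.86 in set 2 between fixed and live Triton cells, by -3.89 and -1.63 between methods in live cells, and by -18.8 and -7.49 in fixed cells. TVAS5 differed by 8.13 by TPM, 26.4 in set 1 and 12.9 in set 2 between fixed and live Triton cells, by -2.58 in set 1 between methods in live cells, and by -12.3 by TPM and -20.2 in set 2 in fixed cells. The neural and radial glia list, in fixed over live FRISCR cells, lay 0.39 above all genes with members from 1 count, the opposite sign, and between -0.72 and 0.12 with 1 cell left out, the last without live FRISCR replicate 12.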

Other observations

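The test of library depth, the test of the S-phase explanation and the look at tRNA-named rows below were chosen only after the results were seen. So was the length implied by the files, with its use in the verdicts. Markers of several other cell types summed to few counts in live cells. Endoderm genes summed to 14.0 CPM in live FRISCR and 8.46 CPM in live Triton cells, mesoderm and primitive streak genes to 62.0 and 64.0 CPM, trophoblast genes to 32.3 and 27.3 CPM, neuron genes to 79.6 and 34.2 CPM and naive-state pluripotency genes to 8.26 and 11.3 CPM. These lists had fewer than 3 members at 5 CPM and were not measured. Neural and radial glia genes (817 and 620 CPM) and fibroblast genes (743 and 709 CPM) had larger sums, but most of their members were low. The median member had 0.055 and 0.73 CPM in the neural and 4.43 and 2.64 CPM in the fibroblast list. At 5 CPM stood 7 and 6 of 16 neural and 5 and 5 of 12 fibroblast members. The neural list shares VIM with the cytoskeleton list, and the fibroblast list THY1 with the cell surface list. Small structured RNA, spike-in and mitochondrially encoded genes were not measured in any comparison. Nor were replication-dependent histones in fixed over live FRISCR cells. The row TVAS5 moved with the MTRNR2L genes, nuclear copies similar to mitochondrial 16S rRNA. Their 10 rows summed to a median of 3.89, 4.01, 3.09 and 3.42 per 100 TVAS5 counts in live FRISCR, fixed FRISCR, live Triton and fixed Triton cells.

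Fixed Triton cells had fewer genes than live Triton cells, and 3 technical explanations were weighed. Library depth is excluded, since the difference was -4530 at equal depth. Crowding out by a few abundant rows is excluded as the whole cause, since without TVAS5, the other unmatched abundant rows and rRNA-named rows, at an equal but smaller depth, the medians were 4973 and 9262, a difference of -4289. Against a loss of long transcripts alone, genes of the shortest 20% by longest transcript were detected in 56.4% and 93.4% of cells on average, a difference of -37.0 percentage points. Detection was not computed by the length implied by the files. By that length the median log2 fold was 0.02 in the shortest 20% (-0.41 in set 1, 0.13 in set 2). In the other bins, from shorter to longer, it was -2.02, -2.16, -1.99 and -1.52. Among these the longest 20% was lowered least, also in each set. Detection by longest transcript in fixed cells was 45.4% in the bin next to the shortest and 51.6% in the longest. Both argue against a loss that keeps growing with length. A loss that spares only the shortest transcripts is neither kept nor excluded, since the lengths part in the shortest bin. Fewer molecules reaching cDNA from each fixed cell could explain the pattern, and was not tested, because no spike-in rows are listed.

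Replication-dependent histone mRNA, rRNA-named rows and MALAT1, which end without a conventional poly(A) tail, were lower in live FRISCR than in live Triton cells. If a missing tail is the reason, histone variants with polyadenylated mRNA should not differ. Those 6 variants, including H2AFZ and H3F3A, lay 0.053 (log2) above all genes, while the 9 replication-dependent genes lay at -6.46, so under-representation of tail-less RNA with FRISCR could be a reason for the histone genes. How these variants move with S phase was not measured, so they cannot tell a missing tail from fewer S-phase cells. Under-representation with FRISCR is not shown for all tail-less RNA. Rows named for tRNA took similar shares, with medians of 0.00051% in live FRISCR and 0.000462% in live Triton cells. These 641 rows summed to only 418 counts in live FRISCR and 290 in live Triton cells, too few to tell whether such RNA was lost. By the G1/S genes, fewer S-phase cells in the FRISCR group can be neither kept nor excluded, since these lay at 0.10, with 0.30 in set 1 and -0.10 in set 2. HIST1H4C reached at most 21.1 CPM in live FRISCR and at least 43.3 CPM in live Triton cells, which speaks against a mere change of mix, but in the share of all these histone genes 14 of 15 live FRISCR cells lay below all live Triton cells. In fixed cells all 12 FRISCR cells lay below all 7 Triton cells in that share, at most 0.0117% against at least 0.0165%. This argues against a change of mix as the whole cause for the histone genes. S phase would name no reason for MALAT1 or rRNA. HIST2H2BE, at a log2 fold of 7.31, and HIST1H2BH, at -0.35, are exceptions to the pattern; the first had counts in only 3 of 15 and 2 of 11 cells.

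Ribosomal protein and oxidative phosphorylation genes were higher than all genes after fixation with both methods, and both have short transcripts. Among random lists matched on length of the longest transcript and on expression, the percentile was 99.99 for ribosomal protein and 100 for oxidative phosphorylation genes with FRISCR, and 100 and 100 with Triton. The longest transcript is a poor length for ribosomal protein genes, with a median of 1857 bases against 3732 for all genes, while the relative length implied by the files is 0.519 against 2.53. With that length the percentile was 24.14 for ribosomal protein and 99.74 for oxidative phosphorylation genes with FRISCR, and 100 and 98.39 with Triton. Transcript length may therefore account for the ribosomal protein genes with FRISCR, which cannot be told from these data. In the other 3 cases the lists lay above random lists matched on either length, which argues against length as the whole cause. For oxidative phosphorylation with Triton the percentile of 98.39 is near the limit. Matching was done within coarse bins of length and expression, so differences inside a bin remain and length is not excluded.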
